A study of Mus musculus with 6 samples.

How the data were processed

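RNA from the pull-down and from the supernatant was labelled in separate reactions with Cy5 and Cy3, 1 ug each, per the labels' protocols, so the red channel holds CLIP RNA and the green channel supernatant RNA on all 6 arrays. The scanner files hold intensity values made with Agilent Feature Extraction 11.0.1.1, per the file headers: the processed signals are background-subtracted and dye-normalised within the array by a linear and a lowess step, with low values replaced by a surrogate. The deposited value table holds log2 values that equal the log2 red processed signal of the same array minus 1 offset per array, which equalled the mean log2 red signal of 7 spike-in probes; its column medians were -3.77, -4.37 and -3.20 for WT 1 to WT 3 and -4.09, -3.28 and -3.50 for PS19 1 to PS19 3. The authors' deposited table of 2380 RNAs gives a log2 fold change, a p-value and an adjusted p-value; recomputing from the value table showed that its direction is PS19 minus WT.

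The files used here pair RNA names with fold changes and not with probes. Names were therefore given to probes by matching the authors' log2 fold change within 1e-09 and p within 1e-07 to values recomputed from single probes, or from means of up to 5 neighbouring microRNA probes. Each of the 2380 names matched 1 of 557616 candidate probe sets and no probe had more than 1 name; for 2377 the probe's code had the class of the name. The other 3 were let-7 names without an arm, whose probes have the precursor code, and they were counted as precursors. The names cover 5637 probes, and 8555 probes stayed unnamed but were tested. Of 223 transcripts named by symbol, 193 matched the mouse gene table of assembly GRCm38.p6 by gene symbol, 149 of them as snoRNAs. They are given here by that gene symbol; the authors' names add a transcript suffix to it.

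Control spots were left out, and log2 processed signals were averaged over the probes of an RNA. An RNA with an outlier spot among its probes has no value on that array, and an RNA counts as well above background where any of its probes is. No spot was saturated. For the CLIP and the supernatant level each array's 75th percentile over the RNAs well above background on all 6 arrays (550 in red, 1703 in green) was subtracted. The log2 ratio of red over green was centred on each array's median, with no loess, since many RNAs of a pull-down can shift one way. RNAs well above background on at least 3 of the 6 arrays, in either channel for the ratio, were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 1 mean per genotype, and called at a Benjamini-Hochberg adjusted p under 0.05. Lists of at least 3 measured RNAs were tested with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests a list against no change and not against other RNAs. Class medians per array were compared with an exact two-sided permutation test. In the CLIP and supernatant levels, an RNA well above background on no array of a group has only a bound, and for the ratio within a genotype the same holds for the supernatant signal. The bound was computed against the higher of its own signal and the lowest signal well above background on each array, and that of the ratio is open to dye bias. The bound of the ratio averages all arrays of a genotype. It is not strict where the CLIP signal was not well above background on each of them.

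RNAs named in the text follow a rule fixed, like the tests and lists, before the data were examined: up to 12 per direction among those that passed with groups that do not overlap, or, where fewer than 5 passed, the 5 with the smallest p; up to 8 per direction for each genotype's ratio; and up to 4 per list. Lists of endothelial and of microglial microRNAs had fewer than 3 RNAs with complete values and were not tested in the CLIP level or the ratio. Alternatives covered background correction, normalisation, scaling, filters, the variance model, blocks, left-out arrays and the authors' values. The normexp alternative was planned on mean signals and run on median signals, the ones used here, before dye normalisation; its offset of 50 lies above the median raw signals, 12 to 33.5, and compresses dim RNAs. The scan of each array was read from the file headers: WT 2 and PS19 1 shared a scan, PS19 2 and PS19 3 shared another, and WT 1 and WT 3 were scanned alone. The scanner voltages in red and green were 386 and 304 for WT 1, 421 and 288 for WT 3, and 420 and 355 for all other arrays.

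The fits were tested on simulated data with 200 changed RNAs and independent noise of the observed size. An 8-fold change was recovered for 40% of the changed RNAs in the CLIP level (2238 RNAs), 96% in the ratio (3842 RNAs) and 80% in the supernatant level (3668 RNAs). A 2-fold change was recovered for 2%, 8% and 4%. The same simulations called 5, 8 and 7 unchanged RNAs. Arrays that share a scan are not independent, as the simulated noise was, so these shares need not hold for the real arrays.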

Results

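Small RNAs pulled down with an antibody to phosphorylated tau (pS396) were measured in the hippocampus of PS19 mice, which carry a human tau transgene with the P301S mutation of inherited frontotemporal dementia, and of wild-type (WT) mice. Tissue was homogenised and crosslinked with ultraviolet light, tau complexes were pulled down with the antibody on magnetic beads (CLIP), and the RNA of the pull-down and of the supernatant left behind was labelled with Cy5 and Cy3 and hybridised together. There were 3 arrays per genotype, each with its own hippocampal sample. The labels do not say how many animals a sample holds. The p-values therefore measure the spread between these samples, which the fit of the CLIP level pooled over RNAs. That spread also holds differences between scans. WT 2 and PS19 1 shared a scan, and PS19 2 and PS19 3 shared another. CLIP levels correlated by at least 0.953 within a scan and by at most 0.822 between scans, while the p-values treat the arrays as independent. The array carried 14192 small RNA probes: 9709 for mature microRNAs, 1767 for tRNA fragments and 2716 for microRNA precursors, tRNAs and small transcripts such as snoRNAs. The share of probes well above background in the CLIP channel was 10.6% on WT 1, 44.2% on WT 2, 24.7% on WT 3, 49.4% on PS19 1, 37.6% on PS19 2 and 42.7% on PS19 3. In the supernatant channel it lay between 35.5% and 63.2%. The number of arrays and this signal over background limit the precision of all values.

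**Figure D1:**
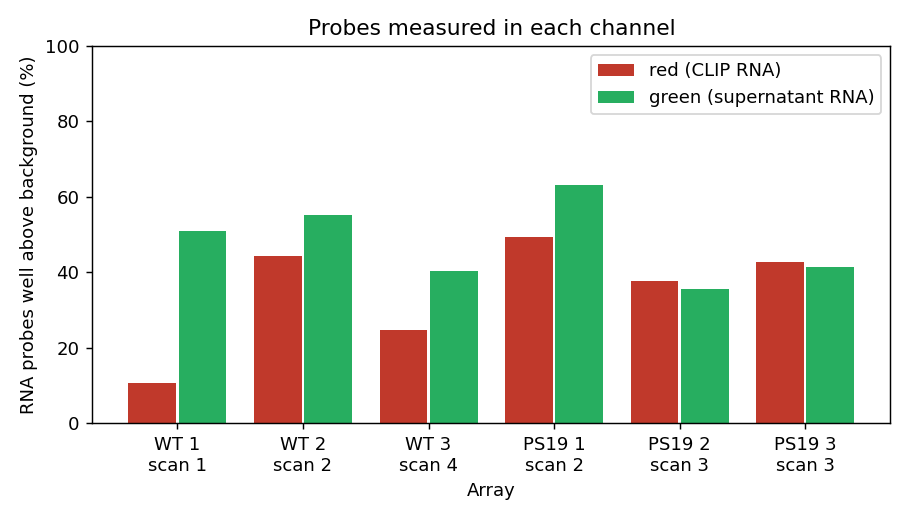
Share of the 14192 RNA probes well above background (vertical axis, percent) in the red channel (CLIP RNA) and the green channel (supernatant RNA) of each array (horizontal axis, with its scan). WT 1 has the lowest red share, 10.6%, and PS19 1 the highest, 49.4%.

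The first comparison asked which small RNAs differed in abundance in the tau pull-down between PS19 and WT hippocampus. No single RNA passed the test. The tRF5 fragments, short pieces from the 5' end of tRNAs, had a higher CLIP level in PS19 than other RNAs did, by a median of 0.26 on the log2 scale over 432 members, of which 298 lay above the median of all RNAs. This shift did not pass with an estimated correlation (adjusted p = 0.968), and inside the scan that held both genotypes its median was -0.0040. Precursor microRNAs, the hairpins from which mature microRNAs are cut, lay 0.49 below the other RNAs over 157 members (median -0.49), snoRNAs, which guide chemical modification of ribosomal RNA, had a median of -0.45 over 132 members, and full-length tRNAs a median of -0.45 over 30 members. Without WT 1 these 3 medians were 0.43, 0.26 and 0.39, in the opposite direction, and without WT 3 they were -1.09, -1.06 and -1.19.

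Of 2356 RNAs tested, 0 had an adjusted p under 0.05 in limma, 45 were higher and 6 lower in PS19 at an unadjusted p under 0.05, and the lowest adjusted p was 0.773. This balance turned with the scaling: 12 were higher and 42 lower with the 75th percentile over all probes, 5 and 21 with spike-in scaling, 71 and 2 with no scaling, and 18 and 27 with normexp background correction. Without WT 2 it was 949 and 9. The groups did not overlap for 124 RNAs, 5.26%, where chance gives 10%. With array quality weights 28 RNAs passed higher and 8 lower, with the scan as a random block, chosen after seeing the data, 11 and 7, and without WT 3 0 and 1. The median log2 difference of all RNAs was 0.85, and it ranged with the scaling from -0.03 with the 75th percentile over all probes to 1.17 with no scaling, so differences of single RNAs in the CLIP level are given relative to 0.85, the median RNA.

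The RNAs with the smallest p in each direction are given as not passing. Those with the same number of values shared 1 SE: 1.04 with 3 arrays per genotype, 1.16 with 2 WT arrays and 1.27 with 2 per genotype. This SE is a spread pooled over RNAs and not the RNA's own. For a given number of values the p therefore only follows the size of the difference. The mature microRNA mmu-miR-8110 differed by 2.53 on the log2 scale (SE 1.04), with a mean of 0.54 ± 1.36 (SD, n = 3) in WT and 3.92 ± 2.06 (SD, n = 3) in PS19. Inside the scan with both genotypes it was 1.56 on PS19 1 and 1.48 on WT 2. Only PS19 2 and PS19 3, which shared another scan, were high, at 4.89 and 5.32. Its difference before the overall one is taken off, 3.38, was 2.59 without WT 1 and 4.56 without PS19 1. The median RNA then differed by 0.64 and 0.56. For mmu-miR-7074-3p, tRF5-18-IleAAT-5 and mmu-miR-92b-3p the CLIP signal was well above background on 3 PS19 arrays and 0 WT arrays, so only bounds can be given: at least 1.61-fold, 2.52-fold and 1.61-fold higher in PS19 before the overall difference is taken off (adjusted p = 0.773 each). Relative to the median RNA the log2 bound of tRF5-18-IleAAT-5 was 0.49, and those of mmu-miR-7074-3p and mmu-miR-92b-3p, -0.17 each, lay below 0. The fragment tRF5-20-SerAGA-3 differed by 1.73 (SE 1.04), with overlapping groups. Its difference before the overall one is taken off, 2.58, was 0.45 without WT 3, where the median RNA differed by 0.47, so it did not exceed the median RNA. On the lower side, the precursor mmu-mir-143, whose mature products are abundant in vascular smooth muscle, differed by -4.15 (SE 1.16), with values on 2 WT arrays, and mmu-mir-350 by -3.77 (SE 1.04). The mature arm mmu-miR-143-5p went the other way, by 1.76 (SE 1.04) before the overall difference is taken off, and did not pass in limma (adjusted p = 0.773). For mmu-mir-143 the difference before the overall one is taken off, -3.30, was -1.42 without WT 1 and -5.17 without WT 3. For mmu-mir-350 the difference before the overall one is taken off, -2.92, was -1.89 without WT 1 and -4.90 without WT 3. The microRNA mmu-miR-6391 differed by -3.93 (SE 1.27), with values on 2 WT and 2 PS19 arrays. The WT values of mmu-mir-143 and mmu-miR-6391 came from WT 1 and WT 3, both scanned alone, so genotype and scan cannot be told apart for them. The snoRNAs Gm24533 and Gm25480 differed by -3.40 (SE 1.16) and -3.19 (SE 1.16), with values on 2 WT arrays and overlapping groups; without WT 1 their differences before the overall one is taken off turned from -2.55 to 0.73 and from -2.34 to 0.98, so WT 1 alone sets their direction.

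Among 41 RNA lists fixed beforehand, limma's camera with a preset correlation of 0.01 placed 5 higher and 3 lower in PS19. The higher ones were tRF5 fragments (adjusted p = 6.96e-05), tRNA fragments as a whole (median 0.15, adjusted p = 0.0012), and the fragments of tRNA-Met (0.45, adjusted p = 0.0012), tRNA-Thr (0.49, adjusted p = 0.0012) and tRNA-Trp (0.57, adjusted p = 0.00989). The lower ones were precursor microRNAs (adjusted p = 4.1e-09), snoRNAs (adjusted p = 3e-08) and tRNAs (adjusted p = 0.00156). Without WT 1, 5 lists passed. They were the tRF5, tRNA-Met, tRNA-Thr and tRNA-Trp fragments and, newly, the tRNA-Cys fragments, lower in PS19 (median -0.35, adjusted p = 0.0153). The 3 lower lists lost their call. The median of tRNA fragments as a whole was 0.018 without WT 1, with no call, that of tRNA-Met fragments 0.18 and that of tRNA-Thr fragments 0.31. The median of tRNAs was -0.17 without PS19 2. The tRNA-Trp fragments did not pass without WT 3 (adjusted p = 0.0913) or without PS19 3 (adjusted p = 0.067). With an estimated correlation 0 of the 41 lists passed, with adjusted p = 0.968 for each of these 8. With the scan as a block, which rests on PS19 1 and WT 2 alone, 0 lists passed and the medians were -0.0040 for tRF5 fragments, 0.11 for precursor microRNAs, 0.14 for snoRNAs and 0.05 for tRNAs.

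Within the tRNA fragments, 22 of 816 members with a tested level, 804 of them with complete values, were higher at an unadjusted p under 0.05 in limma and 0 passed, whether adjusted over all RNAs or adjusted over the list alone. Among the tRF5 fragments, tRF5-20-IleAAT-5 and tRF5-20-LysCTT-17 were well above background on 3 PS19 arrays and 0 WT arrays, and relative to the median RNA their log2 bounds, -0.41 and -0.46, lay below 0 (adjusted p = 0.773 each). Among tRNA-Met fragments, 31 of 39 lay above the median of all RNAs, and 5'tiRNA-36-MetCAT-7 differed by 1.32 relative to the median RNA (SE 1.04). Of the tRNA-Thr fragments 28 of 33 and of the tRNA-Trp fragments 12 of 15 did. The 5' tiRNAs, which angiogenin cuts from tRNAs in the anticodon loop, had a median of -0.03 over 229 members (mean 0.0035, tested as higher, adjusted p = 0.959), and the 3' tiRNAs 0.12 over 51 members (adjusted p = 0.243). The tRF3 fragments had a median of 0.04 (adjusted p = 0.358), the tRF1 fragments 0.09 (adjusted p = 0.701) and the mitochondrial tRNA fragments -0.13 (adjusted p = 0.704).

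**Figure D2:**
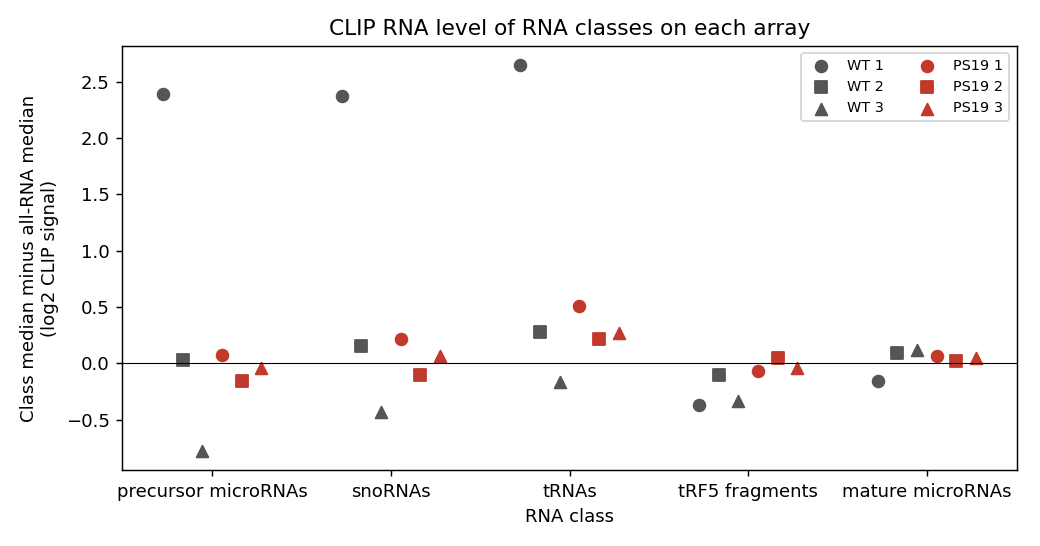
Median log2 CLIP signal of each RNA class minus the median of all RNAs tested (vertical axis) on each of the 6 arrays (points), by class (horizontal axis). WT 1 stands at 2.39 for precursor microRNAs, 2.37 for snoRNAs and 2.65 for tRNAs, where the other arrays lie between -0.78 and 0.51.

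The microRNA lists did not pass in the CLIP level, and for 8 of the 41 lists the median and the mean differed in sign. Mature microRNAs as a class had a median of 0.02 over 1047 members (adjusted p = 0.246). The 13 neuronal microRNA arms had a median of -0.16 (mean 0.03, adjusted p = 0.899). The let-7 family had -0.25 over 8 members (adjusted p = 0.623), and the microRNAs named in tau or Alzheimer work -0.07 over 13 members (mean 0.12, adjusted p = 0.623). Markers of other sources did not pass either: oligodendrocyte microRNAs had 0.29 over 3 members (adjusted p = 0.491), blood microRNAs 0.38 over 7 (adjusted p = 0.353) and choroid plexus microRNAs 0.06 over 8 (adjusted p = 0.533). The C/D box snoRNAs had -0.53 over 5 members (adjusted p = 0.491) and the H/ACA box snoRNAs 0.0049 over 5 (mean -0.09, tested as lower, adjusted p = 0.808).

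The ratio of CLIP to supernatant signal within an array asked which RNAs differed between genotypes in the pull-down relative to the supernatant. Each labelling took 1 ug of RNA and the ratio was centred on each array, so a shift shared by all RNAs cannot be seen. Each sample was pulled down with the tau antibody, with no control antibody or bead-only pull-down. Association with tau therefore cannot be told apart from RNA carried over without it. No RNA passed. The largest differences named by the rule were lower in PS19: the precursor mmu-mir-143 had a mean centred log2 ratio of 2.76 in WT (SD 0.80, n = 2) and of 0.18 in PS19 (SD 0.81, n = 3), a difference of -2.58 (SE 0.60), and the pseudogene transcript Gm26368 had 2.10 ± 1.30 (SD, n = 3) in WT and -0.30 ± 0.21 (SD, n = 3) in PS19. For mmu-mir-143 the WT values came from WT 1 and WT 3, both scanned alone, so genotype and scan cannot be told apart. The mature microRNA mmu-miR-99b-3p differed by -1.53 (SE 0.35), the precursor mmu-mir-5710 by -1.74 (SE 0.48) and the mitochondrial tRNA chrM.tRNA17-SerTGA by -1.46 (SE 0.41). On the higher side, tRF5-22-MetCAT-6 had -0.43 ± 0.33 (SD, n = 3) in WT and 0.92 ± 0.14 (SD, n = 3) in PS19, tRF5-20-IleAAT-5 differed by 1.09 (SE 0.35), the precursor mmu-mir-7034 by 1.19 (SE 0.37), the snoRNA Gm22499 by 1.05 (SE 0.34) and mmu-miR-6546-3p by 1.88 (SE 0.62).

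Of 3971 RNAs tested for the ratio, 0 passed in limma, 83 were higher and 82 lower in PS19 at an unadjusted p under 0.05, and the lowest adjusted p was 0.992. The even balance goes with the centring: with no centring 182 were higher and 32 lower, and with normexp 445 and 192. The groups did not overlap for 354 RNAs, 8.91%, where chance gives 10%. Of the RNAs just named, the CLIP signal of tRF5-22-MetCAT-6, tRF5-20-IleAAT-5 and Gm22499 was well above background on 0 WT arrays, and the supernatant signal of mmu-miR-6546-3p on 0 of the 6 arrays, so the sizes of their differences were not measured exactly; that of mmu-miR-6546-3p was 1.225 without WT 1.

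For the same ratio 0 of 41 lists passed in camera. The lowest adjusted p, 0.0811, was shared by precursor microRNAs (median -0.19 over 152 members) and the fragments of tRNA-Cys (0.18 over 83), tRNA-Met (0.22 over 39) and tRNA-Thr (0.25 over 33). Among the 5' tiRNAs, 5'tiRNA-35-CysGCA-19 differed by 1.31 (SE 0.45) and 5'tiRNA-33-CysGCA-10 by 1.15 (SE 0.42), with adjusted p = 0.992 each. The neuronal microRNA mmu-miR-132-5p, from a locus induced by neuronal activity, differed by -1.06 (SE 0.45, adjusted p = 0.992), and by -0.65 without WT 3. The let-7 family had a median of -0.40 over 8 members (adjusted p = 0.162), with -0.92 (SE 0.46) for mmu-let-7b-5p, which was -0.53 without WT 3. Taken as 1 median per array, the tRNA fragments had a mean of -0.12 ± 0.02 (SD, n = 3) in WT and -0.06 ± 0.08 (SD, n = 3) in PS19 (exact two-sided permutation p = 0.3, adjusted over 9 classes 0.6). The precursor microRNAs had 0.47 ± 0.27 and 0.23 ± 0.12 (exact permutation p = 0.3), the tRNAs 0.41 ± 0.28 and 0.14 ± 0.13 (exact permutation p = 0.3), the snoRNAs 0.41 ± 0.24 and 0.22 ± 0.13 (exact permutation p = 0.4) and the mature microRNAs -0.01 ± 0.02 and -0.02 ± 0.02 (exact permutation p = 0.5). Without WT 1 the differences between genotypes were -0.08 instead of -0.23 for precursor microRNAs, -0.18 instead of -0.27 for tRNAs and -0.05 instead of -0.19 for snoRNAs, and without PS19 2 that of the tRNA fragments was 0.02 instead of 0.06. The smallest p that 3 arrays against 3 can give is 0.1.

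Within each genotype the ratio also showed which RNAs had a higher signal in the pull-down than in the supernatant, relative to the median RNA. The snoRNA Gm23803 (chromosome 10, 59817666 to 59817797, assembly GRCm38.p6) and the microRNAs mmu-miR-206-5p, from a locus best known in skeletal muscle, and mmu-miR-7116-3p passed in both genotypes, and mmu-miR-6546-3p in PS19. Their supernatant signal was well above background on 0 of the 6 arrays, so the sizes in PS19 are bounds. There the pull-down was at least 7.17-fold higher for Gm23803, 6.62-fold for mmu-miR-206-5p, 3.82-fold for mmu-miR-7116-3p and 3.99-fold for mmu-miR-6546-3p. In WT the same calculation gave 5.90-fold for Gm23803, 5.14-fold for mmu-miR-206-5p and 4.39-fold for mmu-miR-7116-3p. These WT values are not strict bounds, since they take in an array whose CLIP signal was not well above background. The CLIP signal of Gm23803, mmu-miR-206-5p and mmu-miR-7116-3p was well above background on 2 WT and 3 PS19 arrays.

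In limma 3 RNAs passed higher in WT and 4 in PS19, and 0 passed lower in either, among 3971 tested. At an unadjusted p under 0.05 there were 173 higher and 144 lower in WT and 123 higher and 152 lower in PS19. The adjusted p was 0.0057 in WT and 0.00255 in PS19 for Gm23803, 0.0213 and 0.017 for mmu-miR-206-5p, 0.0057 and 0.00336 for mmu-miR-7116-3p, and 0.0454 in PS19 for mmu-miR-6546-3p, which did not pass in WT (adjusted p = 0.441). Its difference between genotypes did not pass (adjusted p = 0.992). Without WT 2 and without WT 3, 0 RNAs passed in WT, and in PS19 2 passed without WT 3 and 2 without PS19 2. No array had the dyes swapped, and 0 RNAs passed in either genotype with a variance trend, while with normexp background correction 3 passed in WT, all lower in the pull-down, and 0 in PS19.

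**Figure D3:**
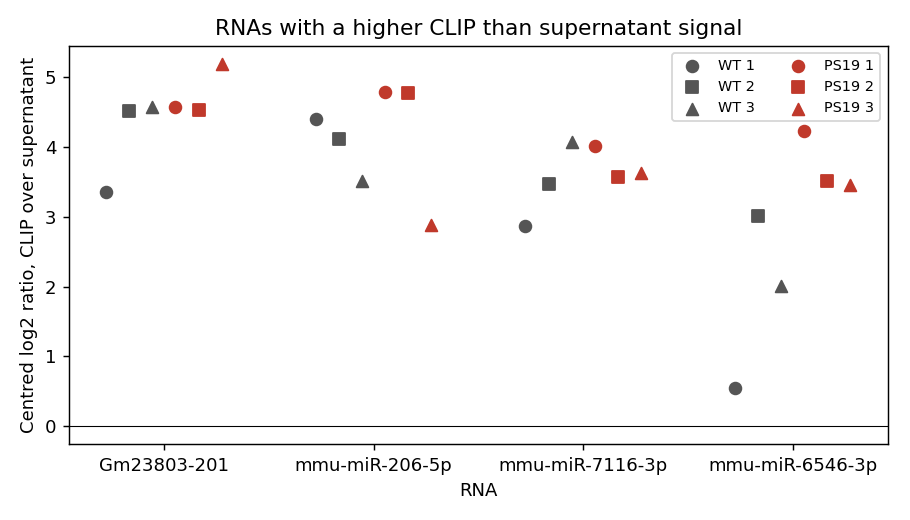
Centred log2 ratio of CLIP over supernatant signal (vertical axis) on each of the 6 arrays (points) for the 4 RNAs that passed in a genotype (horizontal axis). All points lie above 0, the lowest being WT 1 for mmu-miR-6546-3p at 0.54.

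The supernatant level showed whether the unbound RNA pool differed between genotypes. No RNA passed. The median log2 difference of all RNAs was 0.10, and it ranged with the scaling from -0.11 with spike-in scaling to 0.87 with no scaling, so differences are given relative to the median RNA. The fragment tRF5-18-IleAAT-5 differed by 2.24 (SE 0.70) and mmu-miR-7074-3p by 2.54 (SE 0.82), both also among the higher RNAs named for the CLIP level. The fragment 5'tiRNA-36-AsnGTT-3 differed by 1.23 (SE 0.39), mmu-miR-99b-3p by 1.24 (SE 0.40) and 3'tiRNA-41-ArgTCT-1 by 0.92 (SE 0.34). For tRF5-18-IleAAT-5, mmu-miR-7074-3p and 5'tiRNA-36-AsnGTT-3 the supernatant signal was well above background on 1 WT and 3 PS19 arrays. For mmu-miR-99b-3p it was so on 2 WT and 3 PS19 arrays. The sizes of these differences were therefore not measured exactly. On the lower side were the H/ACA box snoRNA Snora35 with -3.51 (SE 0.72) and the microRNAs mmu-miR-7002-5p with -2.75 (SE 0.59), mmu-miR-202-3p with -2.44 (SE 0.37), mmu-miR-710 with -2.41 (SE 0.38) and mmu-miR-1967 with -2.17 (SE 0.40). Each had values on 2 WT arrays because WT 2 had an outlier among their spots. Those were WT 1 and WT 3, scanned alone at green voltages of 304 and 288, against 355 for the PS19 arrays. Genotype cannot be told apart from scan and scanner voltage for these lower RNAs. Of 3727 RNAs tested, 0 passed in limma, 65 were higher and 39 lower at an unadjusted p under 0.05, and the lowest adjusted p was 0.928. This balance turned too: 29 were higher and 87 lower with median scaling, 8 and 36 with spike-in scaling, 94 and 0 with no scaling, and 1716 and 40 with normexp. The groups did not overlap for 385 RNAs, 10.3%, where chance gives 10%.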

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

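The tests of explanations and the splits in this part were chosen after the results were seen, while the arrays left out and the scan block were planned as alternatives. On 50 further probes that carry no small RNA code, 6 had most red spots well above background on all 6 arrays, while 0% of the 77 negative control spots were; this signal lies outside the comparisons above.

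The lower CLIP level of precursor microRNAs, snoRNAs and tRNAs in PS19 argues for a single array rather than the genotype. Without WT 1 the precursor median relative to all RNAs was 0.43 instead of -0.49, and only 1 of the 3 WT arrays had a precursor median above the 3 PS19 arrays, which argues against a decrease shared by the PS19 mice. WT 1 also had the lowest share of red probes well above background. It stood apart in the supernatant too, with class medians of 1.91 for precursor microRNAs, 2.21 for snoRNAs and 2.07 for tRNAs. The other arrays lay at 1.14 or below there, so what sets WT 1 apart was not confined to its dim red channel. A difference between scans may add to the lower CLIP level and cannot be told apart, because the value inside a scan, 0.11, rests on 1 pair of arrays.

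The higher CLIP level of tRF5 fragments in PS19 passed with the preset correlation (adjusted p = 6.96e-05) and not with an estimated one (adjusted p = 0.968), and its adjusted p ranged from 4.08e-11 to 0.995 over all alternatives. Without WT 1 the median was 0.22 instead of 0.26, with an adjusted p of 0.048 with the preset correlation. WT 3 lay as low as WT 1, with tRF5 medians of -0.34 and -0.37, while WT 2 at -0.10 lay next to the lowest PS19 array at -0.07. The shift without WT 1 therefore rests on WT 3, and as a difference between array medians, 0.20 (SE 0.12), it lies within 2 SE of 0, so WT 1 as the only source is made less plausible but cannot be excluded. On WT 1 and WT 3 only 4.81% and 22.9% of the tRNA fragment probes were well above background in red. On the other arrays it was 43.6% to 56.8%. The 2 low arrays are thus those where most of these probes lay near background, and this limit was not tested apart. The supernatant, whose lists were tested after the result was seen, showed a tRF5 median of 0.24 (adjusted p = 3.29e-06 with the preset correlation, 0.741 with an estimated one), close to the CLIP shift. In the ratio of CLIP to supernatant the tRF5 median was smaller, 0.097 over 432 members. It did not pass in camera (adjusted p = 0.166 with the preset correlation, 0.66 with an estimated one). A difference in the RNA pool before the pull-down stays open, since the supernatant shift, like the CLIP shift, holds only with the preset correlation. Scan stays open: inside the scan with both genotypes the median was -0.0040, from 1 pair of arrays, and WT 1 and WT 3 were scanned alone. Taken as 1 CLIP median per array, the PS19 arrays all lay above the WT arrays (exact two-sided permutation p = 0.1, adjusted over 9 classes 0.9). That p is the smallest this design can give. A genotype effect on tRF5 abundance stays open and was not tested apart from WT 1, the RNA pool, scan and background.

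For the RNAs with a higher CLIP than supernatant signal, supernatant signals too low to measure do not make up the whole ratio: with green raised to the lowest measurable level of its array, the lowest log2 ratio of a called RNA was still 1.42 on the arrays of the genotypes in which it was called. This leaves out mmu-miR-6546-3p on the WT arrays, and it takes in WT arrays on which the CLIP signal itself was not well above background. Dye bias cannot be told apart from enrichment, since 0 arrays carried the CLIP RNA in green. With normexp background correction the log2 ratio of Gm23803 was 0.44 in WT and 0.63 in PS19, so the size may depend on how dim signals are treated. Both lie below the log2 values of 2.56 in WT and 2.84 in PS19 behind the fold sizes given above. Those sizes hold only for the processed signals.

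The 10 splits of the 6 arrays are too few for a share under 0.05. Where the real count was 0, any split has at least as many (10 of 10), so that comparison says nothing: this holds for RNAs in the CLIP level (highest other 30), the supernatant level (53) and the ratio (0), and for lists in the ratio (12). For the CLIP lists 9 of 10 splits, the real one among them, had at least the real 8, highest 14. A count of 8 lists with the preset correlation is therefore not particular to the split by genotype. The split with 30 RNAs in the CLIP level and 53 in the supernatant put WT 1, WT 2 and PS19 1 against WT 3, PS19 2 and PS19 3, which keeps each scan on 1 side. The other split that does so, WT 1, PS19 2 and PS19 3 against the rest, had 1 and 0, so these counts of RNAs do not show an effect of scan. The counts of lists were highest in these 2 splits, with 14 and 12 in the CLIP level and 12 and 5 in the ratio. All other splits had at most 11 and 2. List counts were thus highest where a split followed the scans, which 10 splits are too few to test.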

How the results depend on the processing

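Alternatives chosen after seeing the data were the scan as a random block, named RNAs only, and leaving out both arrays scanned alone. The counts of 0 for the ratio and the supernatant level between genotypes held under the alternatives run. The cause of the changes below was not tested. For the CLIP level 0 RNAs became 5 with normexp, 36 with array weights and 18 with the scan as a random block; leaving out 1 array gave 0 to 1. The CLIP lists went from 8 to 0 with normexp, the scan block and an estimated correlation, to 27 with no filter, 4 with RNAs well above background on all 6 arrays and 14 with array weights, and 5 to 13 with 1 array left out. The test fry called 0 lists in the CLIP level and 0 in the ratio; it sets a list against no change and not against other RNAs, so its counts answer another question than those of camera. The ratio lists went from 0 to 21 with normexp, 1 with loess, 18 with no filter, 10 on all 6 arrays and 5 for named RNAs only, and 0 to 11 with 1 array left out. The 3 RNAs called in WT became 6 with spike-in scaling and 0 on all 6 arrays or with a variance trend, and 0 to 3 with 1 array left out. The 4 in PS19 became 10 with spike-in scaling, 2 with the scan as a random block, and 0 with normexp, on all 6 arrays, with a variance trend or without both arrays scanned alone, and 2 to 5 with 1 array left out. With a replicate block the CLIP, ratio and supernatant counts were 0, and the lists 8 and 0. The same-numbered arrays' deviations correlated by -0.0752, -0.515 and 0.315 in the CLIP level and by 0.141, -0.431 and 0.464 in the supernatant level. The same-numbered array was the best partner for numbers 1 and 3 in the supernatant, and for no number in the CLIP level or the ratio. Same-numbered arrays lay in different scans, so this check cannot tell whether the numbers pair the arrays.

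Signs turned as follows, on the log2 scale. In the CLIP level mmu-miR-7074-3p was -0.013 with normexp and Gm25480 0.081 with the scan block; without both arrays scanned alone tRF5-20-SerAGA-3 was -0.39, Gm24533 0.73 and Gm25480 0.98. CLIP lists with the scan block: 3' tiRNAs -0.10, mature microRNAs -0.026, precursors 0.11, snoRNAs 0.14, tRF3 -0.12, tRF5 -0.0040, tRNA fragments -0.032, tRNA-Trp -0.10 and tRNAs 0.048. With 1 array left out they ranged from -0.035 to 0.22 for 3' tiRNAs, -0.22 to 0.032 for 5' tiRNAs, -0.069 to 0.073 for mature microRNAs, -1.09 to 0.43 for precursors, -1.06 to 0.26 for snoRNAs, -0.14 to 0.18 for tRF3, -1.19 to 0.39 for tRNAs, 0.018 to 0.20 for tRNA fragments, 0.18 to 0.62 for tRNA-Met and 0.31 to 0.52 for tRNA-Thr. On all 6 arrays the 3' tiRNAs were -0.25, tRF3 -0.31 and tRNA fragments -0.057. The 5' tiRNAs were 0.38 with no filter, 0.017 with the brightest probe and 0.0084 with array weights, and mature microRNAs -0.013 with the brightest probe. Ratio lists with normexp: precursors 0.26, snoRNAs 0.28 and tRNAs 0.27; with no filter 0.0051, 0.048 and 0.0055; snoRNAs 0.025 with the scan block, and mature microRNAs from -0.037 to 0.0046 with 1 array left out. Class medians of the ratio with normexp were 0.23 for precursors, 0.24 for tRNAs and 0.28 for snoRNAs, and with no filter 0.051, 0.015 and 0.092, and 0.025 for mature microRNAs. Of 1218 values of single RNAs and lists, those of fry included, 1054 kept direction and side of the threshold, 69 lost a call, 52 gained one and 43 turned sign. Signal over background limits the CLIP level, with 10.6% of probes measured on WT 1.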

Other observations

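All results in this part were chosen after the data were seen. Averaged over the 6 arrays without regard to genotype, 8 RNAs had a higher and 2 a lower CLIP than supernatant signal in limma. The fit treats the 6 arrays as independent and was not run with a scan block. Ratios correlated by 0.259 and 0.576 within a scan and by at most 0.203 between scans. The RNAs that passed are therefore open to scan. Besides those named above, the RNAs that passed included mmu-miR-125a-5p, a brain-enriched microRNA, with a mean log2 ratio of 1.73 (SE 0.22) and between 1.25 and 2.51 on the arrays, measured in red on 5 arrays and in green on 6. The microRNA mmu-miR-331-5p passed too, measured in red on 5 arrays and in green on 4, so the size of its ratio was not measured exactly. The precursor mmu-mir-3108 had 1.70 (SE 0.22), measured in red on 5 arrays and in green on 5. The fragment 5'tiRNA-37-AsnGTT-2, with a supernatant signal well above background on 0 of the 6 arrays, was at least 6.03-fold higher in the pull-down in PS19. In WT the same calculation gave 4.89-fold, which is not a strict bound, since its CLIP signal was well above background on 2 of 3 WT arrays. The fragment 3'tiRNA-41-ValCAC-7 was lower, with -1.12 (SE 0.16) and between -1.49 and -0.74 on the arrays, measured in red on 5 arrays and in green on 6.

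The pull-down resembled the supernatant of the same array: across RNAs, which are not independent replicates, the correlation of red and green log2 signals lay between 0.912 and 0.935. Differences between genotypes in the CLIP level and in the supernatant level correlated with r = 0.735 across 2293 RNAs. This says nothing about genotype: the 9 other splits of the 6 arrays gave r between 0.714 and 0.862. Arrays of the same scan had a CLIP level correlation of at least 0.953, and arrays of different scans at most 0.822.

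In the table deposited by the authors, p was under 0.05 for 57 RNAs, 56 of them higher in PS19, and the adjusted p was 0.999 throughout. This balance did not hold in limma with the same spike-in scaling on the RNAs tested here, where 5 were higher and 21 lower at an unadjusted p under 0.05. Of the 57, 24 (42.1%) were tRF5 fragments, against 18.4% of the 2380 RNAs listed (Fisher's exact p = 3e-05, adjusted over 2 classes 6e-05). The tRNA fragments as a whole made up 45.6% of the 57 against 34.3% of the RNAs listed, which did not pass (Fisher's exact p = 0.0891). The test treats RNAs as independent, those with shared sequence included. In the CLIP level the estimated correlation between RNAs was 0.648 for tRF5 fragments and 0.639 for mature microRNAs, so it was not confined to tRNA fragments. With it the tRF5 shift did not pass in camera (adjusted p = 0.968). The Fisher p-values therefore do not measure the spread between samples, and no difference between genotypes is drawn from them.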
